A study of Rattus norvegicus with 46 samples.

How the data were processed

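Per the labels, male F344 rats aged 11 to 12 weeks received a single dose of chlorpyrifos, an organophosphate insecticide whose active metabolite inhibits acetylcholinesterase, and were killed 96 hours later. The doses were 0 (vehicle), 0.5, 1, 5, 10, 30 and 50 mg/kg, spread over 3 separate experiments called A, B and C. About 30 mg of frontal lobe gave the total RNA for 1 Affymetrix rat array per animal, with 15 ug labelled with biotin by an Enzo procedure after Qiagen RNeasy extraction. The deposited table holds 46 arrays and 15923 probe sets, of which 57 are Affymetrix controls.

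The deposited values are linear signal intensity per probe set, with no detection calls. The summarization software is not given in the sources used here. The mean intensity after trimming 2% at each end lay within 1 of 500 in 44 arrays, was 366 in vehicle animal 1 of experiment A and was 205 in the 5 mg/kg animal of experiment B. Signal per array is the only depth such a table holds, and the number of arrays limits the precision.

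Each array was checked against the others by the Pearson correlation over probe sets of log2 intensity, with intensities floored at 16. In 39 arrays the pairwise values lay between 0.935 and 0.979. In the other 7, pairwise values among themselves lay between 0.937 and 0.975, and between the 2 sets they lay between -0.0068 and 0.0025. The 7 arrays are vehicle animal 1, 1 mg/kg animal 4 and 50 mg/kg animal 1 of experiment A, 0.5 mg/kg animal 1 of experiment B, and 5 mg/kg animal 2 and 30 mg/kg animals 1 and 2 of experiment C. Since the 7 share no order of probe sets with the other 39 and no table pairs them, they were left out. The plan had been to use all 46 arrays. This leaves 39 arrays: 3 vehicle, 3 at 1, 5 at 10 and 3 at 50 mg/kg in experiment A; 4 vehicle, 3 at 0.5, 1 at 5 and 3 at 30 mg/kg in experiment B; and 3 vehicle, 4 at 1, 3 at 5 and 4 at 10 mg/kg in experiment C. Groups follow the titles. The vehicle arrays of experiment B carry a second description line naming 1 mg/kg, which their title, source and first line contradict. Vehicle animal 1 and 10 mg/kg animals 2 and 3 of experiment C are labelled as a first repeat, and the labels do not say of what.

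Arrays were scaled to equal medians, floored at the 5th percentile of all scaled values (an intensity of 11.0), log2 transformed and quantile normalized, the last because the medians of the used arrays (112 to 286) spanned 1.35 log2 units against a limit of 0.15. Controls were left out (15866 probe sets), as were probe sets whose mean lay under the 30th percentile, leaving 11106. Symbols came from the platform table: 12783 probe sets carry 1 symbol, 312 several and 2771 none, and 12754 of 12789 with 1 symbol, controls included, matched the gene table by identifier. Probe sets without a single symbol were counted and not named.

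Each probe set was fitted in limma 3.58.1 (R 4.3.3) with experiment as an additive term and dose as a factor, with moderated statistics whose prior followed the mean (trend=TRUE), and Benjamini-Hochberg adjustment over the 11106 at a threshold of 0.05. A second fit took log2(dose + 1) as a number, and a moderated F test asked for a change at any dose. The difference of the 1 and of the 10 mg/kg effect between experiments A and C was tested as a contrast, and the vehicle arrays of the 3 experiments were compared by a moderated F test. Tests of a change are two-sided. Effects of experiments A and C were also correlated over probe sets, against every regrouping of the vehicle and dosed arrays of experiment A. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.

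Gene lists, 32 in all, were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with 1 probe set per gene (the highest mean) and adjustment over the 31 lists with at least 5 measured members. They are cholinergic genes, serine hydrolases that organophosphates can bind, xenobiotic metabolism, immediate early and activity-regulated genes, neurotrophins and growth factors, glutamate receptors and transporters, the GABA system, the monoamine system, neuropeptides, synaptic vesicle and release machinery, G protein and cyclic nucleotide signalling, voltage-gated ion channels, glucocorticoid-responsive genes, circadian clock genes, oxidative stress response, heat shock and unfolded protein response, inflammation, apoptosis and cell cycle, cytoskeleton and axon growth, mitochondrial respiratory chain, ribosomal proteins, proteasome subunits, and markers of astrocytes, oligodendrocytes and myelin, microglia, endothelium, meninges and fibroblasts, choroid plexus, blood, striatum, olfactory bulb and neurons. Some genes stand in more than 1 list.

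Genes were named by a rule. For each dose and the trend it takes the 10 largest changes among those past the threshold with the same direction in each experiment holding the dose, filled up to 10 with the smallest p as values that did not pass. It adds up to 4 members per list with the smallest trend p, and 25 genes named whatever their values. A gene with several probe sets is given by the one with the highest mean. The groups, the tests, the lists, this rule and most alternative settings were set before the data were examined.

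The alternative settings changed the normalization, the floor, the filter, the variance prior, the array weights, the experiment term, the dose scale and the choice of probe set, used a replicate block, and left out each array, each experiment, the 3 arrays labelled as a first repeat and the single 5 mg/kg array of experiment B. Added after seeing the data were all 46 arrays as deposited, median scaling alone, and covariates meant to follow the tissue content of the pieces. The hypothalamic score is the mean of Oxt and Avp. The 3 tissue scores are this one, Ttr for choroid plexus, and the mean of Drd2, Penk and Adora2a for the striatum. Each count, except that of gene lists differing between experiments A and C, was set against up to 100 regroupings of the same arrays (seed 1). The same fit was tested on simulated data over 11106 probe sets. At 50 mg/kg it recovered 44.8% of changes of 0.5, 88.1% of changes of 1 and 100% of changes of 2 on the log2 scale, with 9 false calls. The simulated noise was independent between probe sets, and 67, 67 and 66 probe sets carried changes of these sizes at once. In real pieces, where probe sets vary together and fewer may change, recovery can be lower.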

Results

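The data are log2 normalised intensities of 11106 probe sets in 39 frontal lobe pieces, taken 96 hours after vehicle or a single dose of chlorpyrifos. By the animal numbers of the titles each piece is from a separate rat, though 3 arrays of experiment C are labelled as a first repeat. Vehicle animals were 3 in experiment A, 4 in experiment B and 3 in experiment C. Doses of 1 and 10 mg/kg were held by experiments A and C, 5 mg/kg by B and C, 0.5 and 30 mg/kg by B alone and 50 mg/kg by A alone. Array medians before normalization ran from 112 to 286 units of intensity. Changes below are log2 differences from vehicle ± SE, fitted in limma with experiment as a term, and a gene list's result is the median change of its measured members. For every dose the question was which transcripts and gene groups of the frontal lobe differed from vehicle.

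At 50 mg/kg, Pmch, which encodes the precursor of the hypothalamic peptide melanin-concentrating hormone, rose by 2.24 ± 0.38 (4.71-fold, adjusted p = 0.0156). Its mean was 10.09 ± 1.39 (SD, n = 3) against 7.65 ± 0.16 (SD, n = 3) in the vehicle animals of experiment A, and the 3 dosed arrays read 8.52, 10.61 and 11.14. Tnnc2, the troponin C of fast skeletal muscle, fell by 1.92 ± 0.36 on the log2 scale (0.265-fold, adjusted p = 0.0307), to 6.82 ± 0.26 (SD, n = 3) from 8.73 ± 0.19 (SD, n = 3). These were the only calls of limma at this dose, 1 up and 1 down, with 887 probe sets under an unadjusted p of 0.05 where 555 would be expected by chance. The same counts at 1, 5 and 10 mg/kg were 282, 275 and 298, far under 555. The figure of 555 is therefore no firm reference for these data. Pmch moved with 2 other hypothalamic peptides, chosen after their values were seen. Oxytocin (Oxt) stood at 7.97, 11.64 and 12.21 in the 3 dosed animals against 8.73, 5.62 and 6.25 in vehicle, and vasopressin (Avp) at 8.87, 12.41 and 12.76. High Oxt also occurred at 12.05 in animal 2 at 1 mg/kg of experiment A, where Pmch was 9.13 and Tnnc2 6.91, and at 11.76 in vehicle animal 3 of experiment C, where Pmch was 8.82. Within experiment A alone the changes were 2.43 for Pmch (adjusted p = 0.152) and -1.92 for Tnnc2 (adjusted p = 0.0216). The next 8 genes did not pass (adjusted p from 0.0961 to 0.226). Mink1 was -0.60 ± 0.13, the axonal adhesion gene Cntn4 -0.64 ± 0.14 and the actin regulator Cyfip2 -0.44 ± 0.10. Values were -0.86 ± 0.19 for Rasgef1b, -0.62 ± 0.15 for Mrpl38, -1.61 ± 0.40 for the olfactory receptor Olr59, -0.76 ± 0.19 for the neuronal calcium-binding Necab1 and -1.04 ± 0.26 for the MAP kinase phosphatase Dusp1. Pmch lost its call without vehicle animal 2 (adjusted p = 0.0617) or 3 (0.0860) or dosed animal 3 (0.272) or 4 (0.252) of experiment A. Tnnc2 lost its call without the same vehicle animals (0.110 and 0.104) or dosed animal 2 (0.0521), 3 (0.194) or 4 (0.252). With the mean of Oxt and Avp as a covariate Pmch was 1.21 ± 0.28 and Tnnc2 -1.37 ± 0.37, and neither passed (adjusted p = 0.484 and 1.00). Without experiment C limma called 66 probe sets at this dose, 10 up and 56 down. Neither Pmch nor Tnnc2 passed without experiment B, with no filter on dim probe sets or with a replicate block (adjusted p from 0.0544 to 0.118). Over all alternative settings the adjusted p of Pmch at 50 mg/kg ran from 4.94e-06 to 1.00 and that of Tnnc2 at 50 mg/kg from 0.00206 to 1.00. The highest value of Pmch came from all 46 columns, which put back the 7 that share no order of probe sets with the others. Its next highest adjusted p was 0.628, with 3 tissue scores as covariates.

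**Figure D1:**
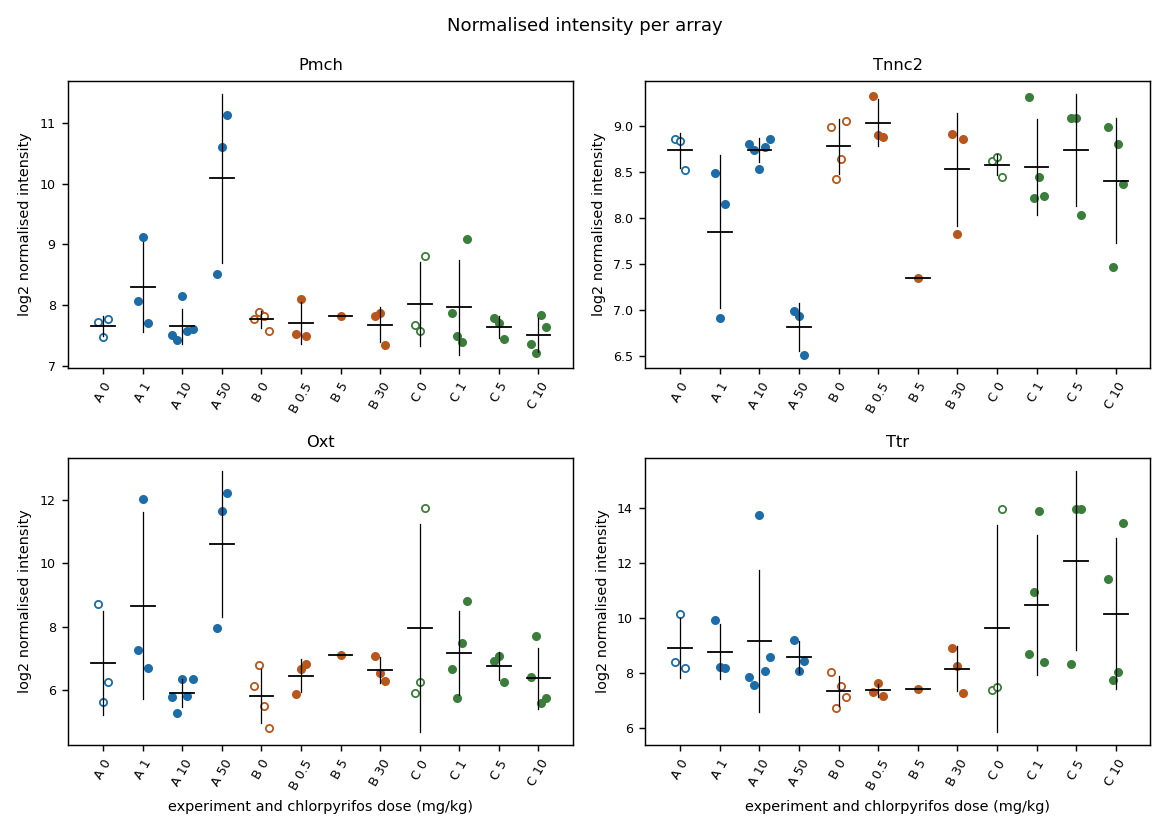
Log2 normalised intensity of Pmch, Tnnc2, Oxt and Ttr in each of the 39 arrays, by experiment (A, B, C) and dose in mg/kg. Open circles are vehicle animals, filled circles dosed animals, lines the mean and bars the SD; at 50 mg/kg Tnnc2 lay between 6.52 and 6.99 in all 3 animals, and Pmch and Oxt were high in 2 of them.

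At 50 mg/kg 13 of 31 gene lists passed with the preset correlation, 6 lower and 7 higher, and none with an estimated correlation. Synaptic vesicle and release machinery fell (25 of 29 members lower, median -0.26, adjusted p = 1.42e-06, and adjusted p = 0.153 with an estimated correlation). In limma 0 of its members passed over all probe sets, 8 had an unadjusted p under 0.05 and 5 passed when adjusted over the list alone. These were the membrane fusion protein Stx1a -0.85 ± 0.23, the active zone proteins Pclo -0.72 ± 0.19, Rims1 -0.63 ± 0.18 and Bsn -0.49 ± 0.15, and the vesicle protein Syn1 -0.36 ± 0.13. List members passing at a single dose are named here and below after their values were seen. Immediate early and activity-regulated genes fell (19 of 24 lower, median -0.31, adjusted p = 1.51e-06, and adjusted p = 0.153 with an estimated correlation). Again 0 passed over all probe sets in limma, 7 had an unadjusted p under 0.05 and 5 passed when adjusted over the list alone. They were Dusp1, the synaptic scaffold Homer1 -0.45 ± 0.13, the activity-regulated Arc (-1.24 within experiment A), the AP-1 factor Junb -0.61 ± 0.21 and the nuclear receptor Nr4a1 -0.85 ± 0.31. Neuropeptides rose (14 of 20 higher, median 0.38, adjusted p = 0.0129, and adjusted p = 0.153 with an estimated correlation). Here 7 passed when adjusted over the list alone, against 1 over all probe sets. Higher members were Pmch, Avp 3.20 ± 0.90, Oxt 3.33 ± 1.08, secretogranin Scg2 0.69 ± 0.25 and galanin (Gal) 0.55 ± 0.21. Lower members were the processing enzyme Pcsk2 -0.56 ± 0.15 and cholecystokinin (Cck) -0.61 ± 0.23. All 3 lists kept their call in each of the 39 leave-one-out fits, but immediate early genes lost it with the hypothalamic score as a covariate. The neuropeptide list, which lost it too, holds Oxt and Avp, the genes of that covariate. The synaptic call held with the covariate, but Stx1a is also among the cortical markers written down after the values were seen, of which 18 of 20 were lower at 50 mg/kg (median -0.42).

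Voltage-gated ion channels were lower as well (26 of 39, median -0.09, adjusted p = 0.00891, and adjusted p = 0.176 with an estimated correlation), with 1 member, the sodium channel Scn8a at -0.96 ± 0.27, passing when adjusted over the list alone. The other lower lists were G protein and cyclic nucleotide signalling (22 of 35 lower, median -0.04, adjusted p = 0.0247), circadian clock genes (12 of 14 lower, median -0.10, adjusted p = 0.0315) and glutamate receptors and transporters (13 of 21 lower, median -0.15, adjusted p = 0.0448). For each of the last 3, adjusted p = 0.176 with an estimated correlation. Higher lists were heat shock and unfolded protein response (22 of 27, median 0.14, adjusted p = 0.00301), oxidative stress response (18 of 23, median 0.10, adjusted p = 0.0110) and olfactory bulb markers (5 of 6, median 0.30, adjusted p = 0.0240), each with adjusted p = 0.189 with an estimated correlation. Tissue markers were higher too, those of astrocytes (15 of 18 higher, median 0.18, adjusted p = 0.00891), of meninges and fibroblasts (14 of 18, median 0.20, adjusted p = 0.0448) and of the striatum (14 of 15, median 0.57, adjusted p = 0.0448). For these adjusted p = 0.243, 0.719 and 0.737 with an estimated correlation. Of the olfactory bulb markers 2 passed when adjusted over the list alone, tyrosine hydroxylase (Th) 0.84 ± 0.24 and calretinin (Calb2) 1.49 ± 0.55. Within experiment A alone, the only one with this dose, the olfactory median was 0.09, with 3 of 6 higher. Without experiment C the olfactory call ended. Leaving out dosed animal 3 ended the calls of G protein signalling, astrocyte markers and voltage-gated channels (adjusted p up to 0.0819) and of circadian genes (up to 0.188, also without vehicle animal 3). Calls also ended for the olfactory list without dosed animal 2 (0.200), for oxidative stress without vehicle animal 3 (0.0516), and for G protein signalling without 1 mg/kg animal 1 of experiment C. Glutamate receptors kept their call in 26, striatal markers in 27 and meningeal markers in 20 of 39 such fits, with highest adjusted p of 0.129, 0.390 and 0.511, while heat shock kept it in all 39. With the hypothalamic score or the 3 tissue scores as covariates the heat shock, voltage-gated channel, G protein, circadian, glutamate, astrocyte and meningeal calls ended. So did the striatal call, whose list shares genes with 1 of the scores. Oxt and Avp, the genes of the hypothalamic score, were chosen after they were seen to be high at this dose. Adjusting for them can shrink a change at 50 mg/kg whatever its cause, so the ended calls do not tell dose from tissue.

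**Figure D2:**
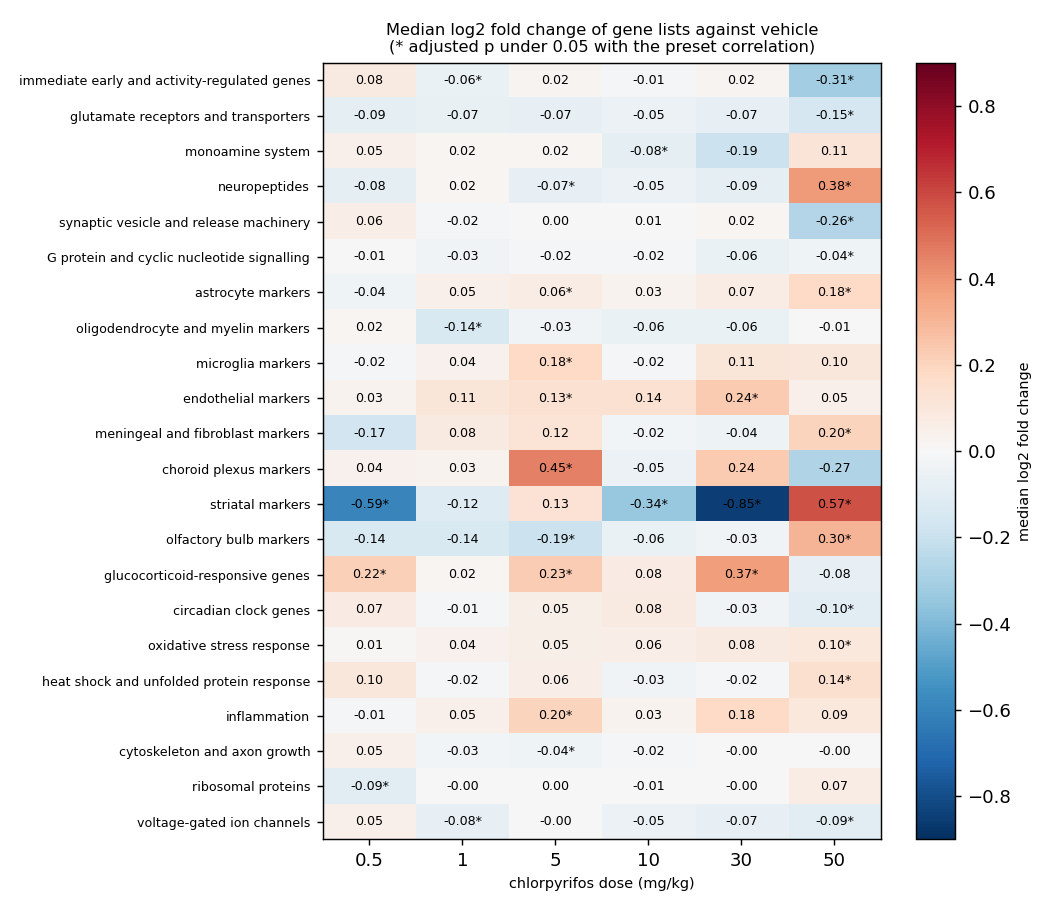
Median log2 fold change against vehicle (colour and printed value) of the 22 gene lists called at 1 or more doses, by dose in mg/kg. Stars mark adjusted p under 0.05 with the preset correlation, a mark no list keeps with an estimated correlation; striatal markers run from -0.85 at 30 mg/kg to 0.57 at 50 mg/kg.

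At 30 mg/kg (3 animals against 4 vehicle animals of experiment B) the genes nearest to passing were Gtpbp2 at 0.47 ± 0.09, the APP-binding adaptor Apba1 at 0.46 ± 0.09 and the phospholipase Plcd1 at 0.48 ± 0.10. Prepronociceptin (Pnoc) was 0.88 ± 0.20, Ccdc85b 0.84 ± 0.18, Rex1bd 0.66 ± 0.14 and Ifrd2 -0.79 ± 0.17. Lower values were those of the BMP receptor Bmpr1a -0.62 ± 0.14, the ciliary transport gene Ift52 -0.91 ± 0.21 and the phosphatase Ptp4a2 -0.49 ± 0.11, whose other probe set had the opposite sign. None of the 10 passed (adjusted p from 0.103 to 0.111). Limma called 0 probe sets, with 1027 at an unadjusted p under 0.05. The beta-actin 3'/5' ratio was 2.15, 1.66, 2.10 and 1.73 in the vehicle arrays of experiment B. It was 1.56, 1.56 and 1.32 at 30 mg/kg, 1.61, 1.37 and 1.34 at 0.5 mg/kg and 1.41 at 5 mg/kg. Every dosed array of B thus lay under every vehicle array, while the Gapdh ratios overlapped. Dose and this ratio run together in B, and what part the ratio has in the changes there was not tested. Striatal markers fell (15 of 15 lower, median -0.85, adjusted p = 2.31e-05, and adjusted p = 0.694 with an estimated correlation), with enkephalin (Penk) at -0.85 ± 0.62 and the dopamine receptor Drd2 at -0.86 ± 0.62. Within experiment B alone the striatal median was -0.65. Glucocorticoid-responsive genes rose (18 of 19 higher, median 0.37, adjusted p = 4.51e-05, and adjusted p = 0.694 with an estimated correlation). In limma 0 of them passed when adjusted over the list alone, against 6 at an unadjusted p under 0.05. Among the 6 were Cebpb 1.22 ± 0.40, Nfkbia 1.36 ± 0.51, the mitochondrial kinase Pdk4 0.43 ± 0.16 and glutamine synthetase (Glul) 0.23 ± 0.09, while Fkbp5 was 0.47 ± 0.29. This list was also called higher at 0.5 and 5 mg/kg, and all 3 calls draw on the same 4 vehicle animals of B. They are therefore not independent. Within B its medians were 0.29, 0.56 and 0.41 at 0.5, 5 and 30 mg/kg. They were -0.08, 0.14 and -0.07 at 1, 10 and 50 mg/kg in A and -0.04, -0.02 and -0.09 at 1, 5 and 10 mg/kg in C. The striatal calls at 0.5 and 30 mg/kg and the endothelial calls at 5 and 30 mg/kg share these vehicle animals too. Endothelial markers rose (12 of 16 higher, median 0.24, adjusted p = 0.0237, and adjusted p = 0.694 with an estimated correlation), with Pecam1 at 0.73 ± 0.25 and the glucose transporter Slc2a1 at 0.60 ± 0.22. Without animal 3 at this dose the glucocorticoid and endothelial calls ended (adjusted p up to 0.227 and 0.643), the endothelial one also without vehicle animal 1, 2 or 3. Without animal 2 at 30 mg/kg limma called 4 probe sets, without vehicle animal 1 of experiment B 2, and without vehicle animal 2 of experiment B or 10 mg/kg animal 1 of experiment A 1.

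At 10 mg/kg (5 animals in experiment A and 4 in experiment C against 3 vehicle animals in each) Cdk7, a kinase that activates other cyclin-dependent kinases, had the lowest p. It was -0.38 ± 0.08 (adjusted p = 0.782), with -0.47 in A and -0.28 in C. The ketone body enzyme Bdh1 was 0.38 ± 0.12, Tlcd3b 0.39 ± 0.11, Klhl8 0.30 ± 0.08, the Notch regulator Dtx1 0.30 ± 0.10 and the nucleotide pool enzyme Nudt1 0.28 ± 0.09. Smaller were Cbarp 0.27 ± 0.07, Nifk 0.24 ± 0.08, the synaptic adhesion gene Lrfn4 0.23 ± 0.07 and Reep5 -0.16 ± 0.05, all 9 with adjusted p = 0.999. Limma called 0 probe sets, with 298 at an unadjusted p under 0.05. Striatal markers fell in the pooled fit (14 of 15 lower, median -0.34, adjusted p = 0.0223, and adjusted p = 0.679 with an estimated correlation), but within experiments their median was 0.15 in A and -0.94 in C. Monoamine system genes fell (15 of 19 lower, median -0.08, adjusted p = 0.0305, and adjusted p = 0.185 with an estimated correlation; -0.09 in A and -0.02 in C). In limma 0 members of either list passed when adjusted over the list alone, against 1 in each at an unadjusted p under 0.05. The striatal call ended without vehicle animal 2 or 10 mg/kg animal 3 or 4 of experiment A, or vehicle animal 1 or 10 mg/kg animal 3 of experiment C (adjusted p up to 0.482). The monoamine call ended without vehicle animal 4 or 10 mg/kg animal 4 of A, the 5 mg/kg animal of B or 10 mg/kg animal 3 of C (up to 0.106). Among the 3 arrays labelled as a first repeat are 10 mg/kg animals 2 and 3 of C. Without these 3 arrays the striatal call ended and the monoamine call held.

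At 5 mg/kg (1 animal in experiment B and 3 in experiment C) the genes with the lowest p included Mertk, a receptor for the clearance of dying cells, at 0.54 ± 0.16 (0.57 in B and 0.56 in C). Another was Hsd11b1, which regenerates active glucocorticoid, at 0.45 ± 0.14 (0.71 and 0.38). The nuclear envelope gene Emd was -0.32 ± 0.09, Nfu1 -0.32 ± 0.09, the phosphodiesterase Pde3b -0.43 ± 0.13 and Syncrip-ps2 -0.47 ± 0.14. Other values were Dnaaf10 0.50 ± 0.15, the phospholipid flippase Atp8a1 -0.25 ± 0.08 and the mRNA decapping gene Edc4 0.21 ± 0.07. None passed (adjusted p = 1.00 for each), and limma called 0 probe sets, with 275 at an unadjusted p under 0.05. Glucocorticoid-responsive genes (17 of 19 higher, median 0.23, adjusted p = 2.42e-04) and choroid plexus markers (7 of 7, median 0.45, adjusted p = 0.00161) rose. So did endothelial markers (15 of 16, median 0.13, adjusted p = 0.00161) and inflammation genes (12 of 16, median 0.20, adjusted p = 0.00547), and all 4 had adjusted p = 0.297 with an estimated correlation. Microglia markers rose (16 of 17, median 0.18, adjusted p = 6.08e-04, and adjusted p = 0.429 with an estimated correlation). Astrocyte markers rose (13 of 18, median 0.06, adjusted p = 0.0392, and adjusted p = 0.466 with an estimated correlation). Cytoskeleton and axon growth genes fell (25 of 34 lower, median -0.04, adjusted p = 0.0392, and adjusted p = 0.466 with an estimated correlation). Olfactory bulb markers (6 of 6 lower, median -0.19, adjusted p = 0.0392) and neuropeptides (15 of 20 lower, median -0.07, adjusted p = 0.0405) also fell, each with adjusted p = 0.297 with an estimated correlation. Of the glucocorticoid-responsive genes 1, Mertk, passed when adjusted over the list alone.

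Within experiments, the 5 mg/kg animal of B and the 3 of C had list medians of 0.56 and -0.02 for glucocorticoid-responsive genes and of 0.69 and 0.02 for microglia markers. They were 0.42 and 0.08 for endothelial markers and 0.41 and 0.15 for inflammation. Astrocyte markers had 0.19 and -0.01, cytoskeleton genes -0.18 and 0.06, olfactory bulb markers -0.09 and -0.23 and neuropeptides -0.07 and -0.20. Choroid plexus markers ran the other way, 0.05 and 0.58, with transthyretin (Ttr) at 13.95 in both of animals 3 and 4 of experiment C. Without the array of experiment B the glucocorticoid, microglia, endothelial and inflammation calls ended (adjusted p up to 0.379, 0.636, 0.636 and 0.219), as did those of astrocyte markers, neuropeptides, olfactory bulb markers and cytoskeleton genes, 8 of the 9 calls at this dose. The microglia, endothelial and inflammation calls also ended without animal 4 of experiment C, and the choroid plexus call ended without animal 3 or 4 of experiment C (up to 0.247). Neuropeptides kept their call in 30, astrocyte markers in 31, olfactory bulb markers in 34 and cytoskeleton genes in 33 of 39 leave-one-out fits (highest adjusted p 0.270, 0.714, 0.0954 and 0.857). Cytoskeleton genes changed direction without the array of experiment B.

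At 1 mg/kg (3 animals in experiment A and 4 in experiment C) the immediate early gene Arc was -0.85 ± 0.24, with -1.47 in A and -0.48 in C, and Junb was -0.50 ± 0.16, with -0.61 and -0.56. Other genes with the lowest p were the stress-response gene Gadd45g -0.49 ± 0.16, Mrps5 -0.41 ± 0.14, and the acetyltransferase Kat6b -0.40 ± 0.12. Smaller values were the nuclear pore gene Nup205 -0.27 ± 0.09, Tnrc6c -0.25 ± 0.08, Mapk1ip1 -0.21 ± 0.07, the centrosome gene Cetn2 0.26 ± 0.07 and the peroxisomal enzyme Crot 0.26 ± 0.08. None passed (adjusted p = 1.00 for all 10). Limma called 0 probe sets, with 282 at an unadjusted p under 0.05. Immediate early genes fell as a list (18 of 24 lower, median -0.06, adjusted p = 5.51e-04, and adjusted p = 0.840 with an estimated correlation; medians -0.28 in A and -0.03 in C). In limma 0 passed over all probe sets, while 5 had an unadjusted p under 0.05 and 5 passed when adjusted over the list alone. These were Arc, Junb, Fos -1.07 ± 0.36, Dusp1 -0.56 ± 0.20 and Nr4a1 -0.66 ± 0.23. Oligodendrocyte and myelin markers fell (15 of 16 lower, median -0.14, adjusted p = 5.51e-04, and adjusted p = 0.860 with an estimated correlation), with medians of -0.00 in A and -0.30 in C. Voltage-gated ion channels fell (31 of 39 lower, median -0.08, adjusted p = 0.0433, and adjusted p = 0.840 with an estimated correlation). Oxt was 12.05 in 1 of these animals, animal 2 of experiment A. Without that animal or vehicle animal 3 of A the immediate early call ended (adjusted p up to 0.102), and without experiment A its direction turned. The myelin call ended without vehicle animal 3 or 1 mg/kg animal 1 of experiment C (up to 0.301), whose beta-actin and Gapdh 3'/5' ratios were 4.72 and 2.42. The voltage-gated channels kept their call in 28 of 39 leave-one-out fits (up to 0.287).

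At 0.5 mg/kg (3 animals against 4 vehicle animals of experiment B) the histone deacetylase Hdac1 was -1.46 ± 0.33, the TNF receptor Tnfrsf1a -1.29 ± 0.33, the mitochondrial RNA enzyme Pnpt1 -1.26 ± 0.33 and Srarp -1.90 ± 0.44. Pdk4, which restrains pyruvate oxidation, was 0.61 ± 0.16, Dtx1 0.60 ± 0.14, and Rai14 0.57 ± 0.14. The leukocyte surface protein Cd48 was -0.59 ± 0.14, Ccdc90b -0.39 ± 0.10 and the translation factor Eif4g2 -0.39 ± 0.10, whose other probe set had the opposite sign. None passed (adjusted p from 0.306 to 0.351). Limma called 0 probe sets, with 846 at an unadjusted p under 0.05. Ribosomal protein genes (36 of 40 lower, median -0.09, adjusted p = 0.00113) and striatal markers (14 of 15 lower, median -0.59, adjusted p = 0.0279) fell. Glucocorticoid-responsive genes rose (16 of 19 higher, median 0.22, adjusted p = 0.0201), with Pdk4 passing when adjusted over the list alone. For all 3 lists adjusted p = 0.945 with an estimated correlation. Within experiment B alone the ribosomal median was -0.04, with 29 of 40 lower, and the striatal median was -0.39. Without animal 2 at this dose all 3 calls ended. The ribosomal call also ended without experiment C and without the 5 mg/kg animal of experiment B (adjusted p up to 0.176), and the glucocorticoid call without vehicle animal 2 or 3 of B or dosed animal 4 (up to 0.119). The striatal call also ended without vehicle animal 2 of B, dosed animal 4, the 5 mg/kg animal of B or 5 mg/kg animal 1 of C (up to 0.977). Without dosed animal 3 limma called 5 probe sets, and without dosed animal 2 it called 1.

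Striatal markers had medians of 0.51, 0.15 and 0.87 at 1, 10 and 50 mg/kg in A. In B they were -0.39, 0.98 and -0.65 at 0.5, 5 and 30 mg/kg, and in C -0.90, -0.65 and -0.94 at 1, 5 and 10 mg/kg. Pieces differed in other regional markers as well. The choroid plexus gene Ttr stood at 13.73 in 10 mg/kg animal 3 of experiment A and at 13.95, 13.88 and 13.45 in vehicle animal 3, 1 mg/kg animal 3 and 10 mg/kg animal 4 of experiment C.

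**Figure D3:**
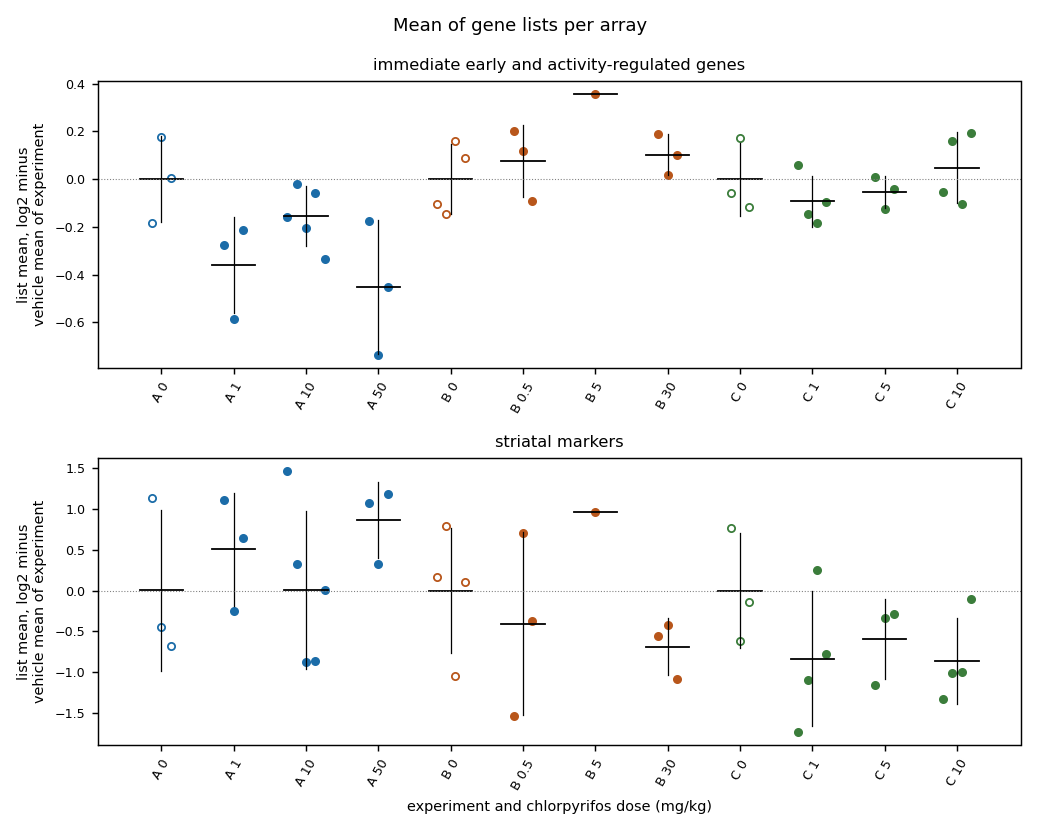
Mean of the immediate early list and of the striatal list in each array, in log2 units minus the mean of the vehicle animals of the same experiment, by experiment and dose in mg/kg. Open circles are vehicle animals, filled circles dosed animals, lines the mean and bars the SD; vehicle animals of 1 experiment spread as widely on the striatal list as dosed animals.

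Across all doses, the question was which genes followed log2(dose + 1) within experiments. The steepest of the 10 slopes with the lowest p were Raver1 at -0.21 ± 0.05 per unit and the splicing gene Snrpn at 0.16 ± 0.03 (0.13, 0.19 and 0.17 in A, B and C). Slopes were -0.13 ± 0.03 for the synaptotagmin Syt11, -0.11 ± 0.03 for the calcium channel subunit Cacnb3, -0.09 ± 0.02 for Dhdds and -0.08 ± 0.02 for the deubiquitinase Usp7. They were -0.08 ± 0.02 for Cdc42bpa, 0.07 ± 0.02 for Mpp3, 0.05 ± 0.01 for Babam1 and 0.04 ± 0.01 for Edc4. Each had the same sign in all 3 experiments, and none passed (adjusted p from 0.135 to 0.233). Limma called 0 probe sets for the trend, with 851 at an unadjusted p under 0.05, and 0 in the test of any dose (687; lowest adjusted p 0.203). Without experiment C it called 100 for the trend, 15 up and 85 down, and 19 at any dose.

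Of 31 lists 8 passed for the trend, 5 sloping down with dose and 3 sloping up. Synaptic vesicle and release machinery fell (22 of 29 lower, median slope -0.02, adjusted p = 0.00168, and adjusted p = 0.390 with an estimated correlation), with Syt11 and Rph3a, -0.15 ± 0.05, passing when adjusted over the list alone. Within experiment C this list was higher than vehicle at every dose, with medians of 0.10, 0.15 and 0.14 at 1, 5 and 10 mg/kg. G protein and cyclic nucleotide signalling fell (29 of 35 lower, median slope -0.01, adjusted p = 0.00168, and adjusted p = 0.0643 with an estimated correlation). The inhibitory subunit Gnai2, -0.09 ± 0.02, passed when adjusted over the list alone, and Gnao1 was -0.05 ± 0.02. Voltage-gated ion channels fell (25 of 39 lower, median slope -0.01, adjusted p = 0.00505, and adjusted p = 0.163 with an estimated correlation). Cacnb3 and Kcna6, -0.10 ± 0.03, passed when adjusted over the list alone, and Kcnq3 was -0.06 ± 0.02. Glutamate receptors and transporters fell (16 of 21 lower, median slope -0.01, adjusted p = 0.0118, and adjusted p = 0.113 with an estimated correlation). The metabotropic receptor Grm3, -0.12 ± 0.04, passed when adjusted over the list alone, and the vesicular glutamate transporter Slc17a7 was -0.08 ± 0.03. Monoamine system genes fell (13 of 19 lower, median slope -0.02, adjusted p = 0.0482, and adjusted p = 0.240 with an estimated correlation), with monoamine oxidase Maoa at -0.05 ± 0.02. At the top dose this list was higher, its medians in experiment A being 0.08, -0.09 and 0.13 at 1, 10 and 50 mg/kg. In B they were 0.02, -0.12 and -0.21 at 0.5, 5 and 30 mg/kg, and in C -0.03, 0.00 and -0.02 at 1, 5 and 10 mg/kg. Astrocyte markers rose (16 of 18 higher, median slope 0.02, adjusted p = 0.00103) and so did oxidative stress genes (20 of 23, median slope 0.02, adjusted p = 0.00351), each with adjusted p = 0.163 with an estimated correlation. Within experiment C astrocyte medians were -0.05, -0.01 and -0.01 at 1, 5 and 10 mg/kg. Of the astrocyte markers Glul and Aldoc, both 0.04 ± 0.01, passed when adjusted over the list alone, beside Ndrg2 at 0.04 ± 0.02 and Apoe at 0.02 ± 0.01. Among stress genes heme oxygenase Hmox1 was 0.04 ± 0.02, Mt3 0.03 ± 0.01 and Gpx1 0.05 ± 0.03. Endothelial markers rose (13 of 16 higher, median slope 0.02, adjusted p = 0.0125, and adjusted p = 0.390 with an estimated correlation), with Slc2a1 at 0.06 ± 0.03. Their medians in experiment A were 0.04, -0.01 and -0.01 at 1, 10 and 50 mg/kg, with no rise at the top dose. In B they were 0.04, 0.42 and 0.29 at 0.5, 5 and 30 mg/kg, and in C 0.08, 0.08 and 0.05 at 1, 5 and 10 mg/kg. In limma 0 genes of these lists passed over all 11106 probe sets. The endothelial call ended without 30 mg/kg animal 3 of experiment B (adjusted p = 0.226), and the monoamine call held in 19 of 39 leave-one-out fits (up to 0.149). Without experiment A the synaptic, G protein, voltage-gated, astrocyte, glutamate and oxidative stress calls ended, and without B the G protein, voltage-gated, glutamate, monoamine and endothelial calls, the last 2 also without C.

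None of the genes of organophosphate biology named in advance passed at any dose. Butyrylcholinesterase (Bche) ran from -0.17 ± 0.12 at 1 mg/kg to 0.23 ± 0.16 at 0.5 mg/kg, and was -0.10 ± 0.16 at 50 mg/kg. The muscarinic receptor Chrm2 was highest at 10 mg/kg, 0.29 ± 0.14, and Chrm1 lowest at 50 mg/kg, -0.86 ± 0.60. The nicotinic receptor Chrna7, the lactonase Pon2 and the monoacylglycerol lipase Mgll were 0.21 ± 0.15, -0.15 ± 0.12 and 0.34 ± 0.20 at 0.5 mg/kg and -0.01 ± 0.15, 0.12 ± 0.12 and 0.05 ± 0.20 at 50 mg/kg. Cholinergic genes as a list (13 measured) did not pass at any dose, with adjusted p of 0.857, 0.708, 0.923, 0.602, 0.976 and 0.952 from 0.5 to 50 mg/kg; at 0.5 mg/kg their median was 0.13 and their mean -0.03. Chat and Pon1 lay under the intensity filter, and Ache, Faah and Pnpla6 had no probe set with a single symbol. The neurotrophin Bdnf was -0.66 ± 0.27, Egr1 -0.34 ± 0.18 and Fos -1.05 ± 0.49 at 50 mg/kg. At the same dose the astrocyte gene Gfap was 0.30 ± 0.20, the microglial Aif1 0.10 ± 0.17, the myelin gene Mbp -0.03 ± 0.11, Hmox1 0.29 ± 0.15, Penk 0.89 ± 0.61 and Drd2 0.57 ± 0.61. Globin (Hbb) ran from -0.83 ± 0.53 at 30 mg/kg to 0.29 ± 0.37 at 10 mg/kg and Ttr from -0.27 ± 1.41 at 50 mg/kg to 1.58 ± 1.19 at 5 mg/kg.

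Experiments A and C both gave 1 and 10 mg/kg, which asks whether a dose did the same in separate groups of rats. Of the list differences at 10 mg/kg myelin markers had the lowest p, with medians of 0.27 in A and -0.44 in C (adjusted p of the difference 2.15e-12, and adjusted p = 0.252 with an estimated correlation). Ribosomal proteins had the next lowest p, at 0.06 and -0.15 (adjusted p = 5.95e-10, and adjusted p = 0.359 with an estimated correlation). The gap was wider in striatal markers, 0.15 in A and -0.94 in C (adjusted p = 0.00488, and adjusted p = 0.480 with an estimated correlation). At 1 mg/kg striatal markers were 0.51 in A and -0.90 in C (1.75e-05, and adjusted p = 0.578 with an estimated correlation). No single probe set differed in limma: 0 at 10 mg/kg (735 at an unadjusted p under 0.05) and 0 at 1 mg/kg (816); without vehicle animal 2 of experiment C 2 did at 10 mg/kg. Across probe sets, which are not independent replicates, the effects of A and C correlated at r = -0.151 (Spearman -0.158) at 10 mg/kg and at r = -0.217 (Spearman -0.208) at 1 mg/kg. In exact permutation tests over 56 and 20 regroupings of experiment A the two-sided p was 0.125 and 0.1, the smallest possible being 0.0179 and 0.1. Without vehicle animal 3 of experiment C r at 10 mg/kg was -0.0386.

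Vehicle animals of the 3 experiments were compared to size the difference between experiments. Limma found 733 probe sets that differed, with 2719 at an unadjusted p under 0.05. Grm3 averaged 8.997 ± 0.16 (SD, n = 3) in A, 10.38 ± 0.14 (SD, n = 4) in B and 9.36 ± 0.19 (SD, n = 3) in C (adjusted p = 0.00135). Gnai2 averaged 10.17 ± 0.24, 10.71 ± 0.27 and 10.00 ± 0.25 (adjusted p = 0.0445) and Maoa 9.75 ± 0.19, 10.26 ± 0.18 and 9.58 ± 0.19 (adjusted p = 0.0217). These 3 genes, which also had negative dose slopes, were chosen here after their values were seen. The count was 215 without vehicle animal 3 of C, which held high Oxt and Ttr, and 438 or 439 without vehicle animal 2 or 1 of C. It was 261, 455 and 322 without vehicle animal 1, 3 or 4 of B. The first principal component over all 39 arrays held 18.0% of the variance, and experiment accounted for 83.3% of it.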

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

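Among tests in this part, the search for single arrays far from their group covered 128 measures, mostly genes named in the text, of which some were tested only after their values were seen. In the 4 groups of 4 or 5 arrays, 1 array stood far from the rest in 36 of 512 combinations of measure and group (7.03%), where chance gives about 1 in 20. Vehicle animal 2 of experiment B held 9 of the 36. In that animal, with the range of the other 3 in brackets, Slc17a7 was 11.81 (12.76 to 12.82), Stx1a 10.13 (11.09 to 11.24), Syn1 11.85 (12.20 to 12.24) and Syt11 9.89 (10.83 to 11.00). Gnai2 was 10.30 (10.82 to 10.89), Egr1 11.22 (11.52 to 11.58), Ift52 8.74 (9.11 to 9.13) and Snrpn 6.60 (7.36 to 7.49), and the choline transporter Slc5a7 was high at 8.60 (6.70 to 6.82). In vehicle animal 3 of B Th was 7.98 (7.06 to 7.19) and Mpp3 8.99 (9.40 to 9.47), and in vehicle animal 4 Avp was 6.97 (7.47 to 7.54).

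In experiment A at 10 mg/kg, Ttr was 13.73 in animal 3 (others 7.57 to 8.58) and Pmch 8.14 (7.43 to 7.61). Animal 1 of that group had Ifrd2 at 8.62 (9.65 to 9.81), Gadd45g at 6.18 (6.93 to 7.07) and Ccdc90b at 8.49 (8.69 to 8.76), and animal 2 Lrfn4 at 9.03 (8.60 to 8.64). In experiment C at 1 mg/kg, animal 1 had a beta-actin 3'/5' ratio of 4.72 (1.24 to 1.37) and a Gapdh ratio of 2.42 (1.14 to 1.26), with Apoe at 12.95 (13.45 to 13.51) and Cntn4 at 8.17 (8.34 to 8.35). Animal 2 had Fkbp5 at 9.39 (8.33 to 8.42), Pnoc at 7.49 (7.32 to 7.35) and Cyfip2 at 11.85 (11.70 to 11.72). Animal 3 had Gadd45g at 5.98 (6.86 to 6.92), Apba1 at 10.53 (10.78 to 10.83) and Gnao1 at 11.34 (10.82 to 10.90).

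In experiment C at 10 mg/kg, animal 2 had Hbb at 13.27 (11.49 to 11.73) and animal 1 Tnfrsf1a at 6.84 (7.88 to 7.99). Animal 3 had Dusp1 at 9.91 (9.38 to 9.45), Hsd11b1 at 10.19 (9.84 to 9.87) and Pdk4 at 7.52 (7.78 to 7.83). Animal 4 had Necab1 at 6.97 (7.88 to 7.90), Nup205 at 8.50 (8.26 to 8.30) and a beta-actin ratio of 1.83 (1.34 to 1.40).

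The same dose gave different list medians in experiments A and C for 12 lists at 10 mg/kg and 7 at 1 mg/kg, by a test of the difference. These counts were not set against regroupings of the arrays, so how many lists chance would give is not known. At 10 mg/kg, given as A, C and adjusted p, oligodendrocyte and myelin markers were 0.27, -0.44 and 2.15e-12, ribosomal proteins 0.06, -0.15 and 5.95e-10, and neuron markers -0.06, 0.14 and 5.53e-04. Cytoskeleton and axon growth genes were -0.09, 0.07 and 8.66e-04, synaptic vesicle and release machinery -0.10, 0.14 and 0.00101, and the mitochondrial respiratory chain 0.06, -0.08 and 0.00125. Striatal markers were 0.15, -0.94 and 0.00488, glucocorticoid-responsive genes 0.14, -0.09 and 0.00650, microglia markers -0.36, 0.15 and 0.0106, and inflammation genes -0.12, 0.16 and 0.0106. Immediate early genes were -0.12, 0.02 and 0.0116, and astrocyte markers 0.11, -0.01 and 0.0146. No list passed at this dose with an estimated correlation, the lowest being adjusted p = 0.252 with an estimated correlation.

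At 1 mg/kg, in the same order, ribosomal proteins were 0.06, -0.14 and 1.65e-09, striatal markers 0.51, -0.90 and 1.75e-05, and oligodendrocyte and myelin markers -0.00, -0.30 and 8.27e-04. Neuron markers were -0.10, 0.14 and 0.00143, synaptic vesicle and release machinery -0.12, 0.10 and 0.00143, immediate early genes -0.28, -0.03 and 0.0135, and astrocyte markers 0.10, -0.05 and 0.0417. The lowest of these with the other setting was adjusted p = 0.412 with an estimated correlation.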

How the results depend on the processing

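Of the alternatives, all 46 columns, median scaling only and both tissue covariates, with their tests, were chosen only after the result was seen. No called gene reversed its direction. The calls at 10 mg/kg, 2 lists lower, became 1 higher with values as deposited and 3 higher with all 46 columns, and those at 0.5 mg/kg, 1 higher and 2 lower, became 2 higher with no experiment term. Of lists with a call, the direction turned for immediate early genes and myelin markers at 1 mg/kg without experiment A or C, cytoskeleton genes at 5 mg/kg without experiment B or its array at that dose, neuropeptides at 5 mg/kg with values as deposited, and striatal markers at 0.5 and 50 mg/kg with 3 tissue scores, 1 of which is made of striatal genes. With all 46 columns it turned for astrocyte markers (trend and 5 mg/kg) and oxidative stress genes (trend). Counts stayed within 1.5 times their value with log2(value + 16), a constant variance prior, the experiments holding each dose alone, other dose scales and the mean of a gene's probe sets. For named genes, 3714 values over the alternatives that change more than 1 array or a setting and 7950 with 1 array left out kept their direction and side of the threshold. In the same order, 104 and 15 changed sign without passing in either fit, 48 and 12 newly passed and 15 and 9 no longer passed. Unless stated, the cause was not tested.

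With an estimated inter-gene correlation 0 gene lists passed in camera for the trend and at each dose, with 6 at an unadjusted p under 0.05 for the trend and 0, 0, 3, 2, 1 and 7 at 0.5, 1, 5, 10, 30 and 50 mg/kg. With values as deposited limma called 5115 probe sets at 5 mg/kg, all lower, the 5 mg/kg array of experiment B having been deposited dimmer, 1 at 50 mg/kg, and 1 and 11 lists at 10 and 30 mg/kg. With median scaling only it called 1 at 50 mg/kg. With no filter on dim probe sets it called 2 at 0.5, 10 at 30 and 0 at 50 mg/kg (1139 at an unadjusted p under 0.05), 382 between vehicle controls, and 1 list at 10 mg/kg. A filter at the 50th percentile, which tests fewer probe sets, gave 1 at 50 mg/kg, and 4, 1 and 4 lists for the trend and at 0.5 and 5 mg/kg. Array weights gave 19 at 30 and 13 at 50 mg/kg, 5 at any dose, 3 for the trend and 5 lists at 1 mg/kg. No experiment term gave 1 at any dose and 5 and 8 lists at 10 and 50 mg/kg.

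Without experiment A, 1 probe set passed at 30 mg/kg and 1 for the trend, and 8 lists at 10 mg/kg. Without experiment B, 0 passed in limma at 50 mg/kg (775 at an unadjusted p under 0.05) and 1 for the trend, with 4, 4 and 1 lists for the trend and at 5 and 10 mg/kg. Without experiment C, 66 passed at 50 mg/kg (10 up, 56 down), 100 for the trend (15 up, 85 down), 6 at 30 mg/kg and 19 at any dose, with 1, 15 and 17 lists at 0.5, 5 and 10 mg/kg. Without the 3 first-repeat arrays 7 lists passed at 10 mg/kg, and without the 5 mg/kg array of experiment B 5 at 5 mg/kg. All 46 columns gave 1 at 30 mg/kg, 0 in limma at 50 mg/kg (86 at an unadjusted p under 0.05) and 0 between vehicle controls (362), r = -0.0185 between A and C at 10 mg/kg, and 1, 4 and 7 lists for the trend and at 5 and 50 mg/kg. The hypothalamic score as a covariate gave 0 at 50 mg/kg in limma (372) and 3 lists there. The 3 tissue scores gave 3 at 30 and 0 at 50 mg/kg (418), and 1, 5 and 4 lists at 0.5, 10 and 50 mg/kg.

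With a replicate block limma called 0 at 50 mg/kg (790 at an unadjusted p under 0.05), and 1 and 4 lists passed at 0.5 and 10 mg/kg. The numbers do not pair the samples: median r was 0.0035 over 43 pairs with the same animal number and 0.0029 over 135 with different numbers.

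With 1 of 39 arrays left out, counts ranged from 0 to 5 at 0.5 mg/kg, 0 to 0 at 1, 5 and 10, 0 to 4 at 30 and 0 to 5 at 50 mg/kg, 0 to 1 at any dose, 0 to 2 for the trend, 0 to 2 and 0 to 0 for the difference of A and C at 10 and 1 mg/kg, and 215 to 904 between vehicle controls. The count at 50 mg/kg was 0 without vehicle animal 2 or 3 or dosed animal 3 of A, 5 without vehicle animal 4 and 4 without dosed animal 2. The trend count was 2 without 0.5 mg/kg animal 4, and that for any dose 1 without 50 mg/kg animal 2 or 0.5 mg/kg animal 2 or 3. The correlation of A and C ranged from -0.223 to -0.0386 at 10 mg/kg and from -0.273 to -0.141 at 1 mg/kg.

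Lists ranged from 7 to 12 for the trend, 0 to 7 at 0.5, 1 to 4 at 1, 4 to 16 at 5, 0 to 8 at 10, 2 to 6 at 30 and 8 to 15 at 50 mg/kg. At 0.5 mg/kg they were 0, 7 and 1 without dosed animal 2, 3 or 4, 1 and 5 without vehicle animal 2 or 4 of B, and 1 without the 5 mg/kg array of B. At 1 mg/kg they were 1 without animal 2 of A. At 5 mg/kg they were 16 and 4 without animal 1 or 4 of C and 5 without the array of B. At 10 mg/kg they were 1 and 4 without dosed animal 4 or vehicle animal 3 of A, 8 and 5 without vehicle animal 2 or 3 of C, and 7 and 0 without dosed animal 1 or 3 of C. At 30 mg/kg they were 6 and 5 without animal 2 or 4 and 5 without the 5 mg/kg array of B, and at 50 mg/kg 8 without vehicle animal 3 of A.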

Other observations

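The splits of the arrays were set in advance, while the other tests of this part, on Pmch, on the immediate early genes and on the 7 columns left out, were chosen only after the result was seen. Where the real count of probe sets was 0, every split of the same arrays gives as many, so the splits say nothing about chance there. This holds for 35 of 35 splits at 0.5 and 30 mg/kg, with at most 3 and 60 in another split, and for 100 of 100 at 1, 5 and 10 mg/kg, with at most 3, 20 and 1. For the trend, any dose and the difference of A and C at 10 and 1 mg/kg it holds for 100 of 100 as well, with at most 10, 12, 2 and 34. Splits that call 20, 34 or 60 probe sets where the real one calls 0 point to a structure of the samples, whose source was not tested.

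For gene lists at 0.5, 1, 5, 10 and 30 mg/kg and for the trend chance could not be excluded. The counts of splits here and above include the real grouping. As many lists passed in 26 of 35 splits at 0.5 mg/kg (real 3, highest other 10), 96 of 100 at 1 mg/kg (3 and 14), 30 of 100 at 5 mg/kg (9 and 18) and 93 of 100 at 10 mg/kg (2 and 15). It was 30 of 35 at 30 mg/kg (3 and 17) and 18 of 100 for the trend (8 and 11), and the highest counts at 1, 10 and 30 mg/kg point again to such a structure. At 50 mg/kg the 10 splits are too few for a share under 0.05: 1 of 10 gave as many probe sets (real 2, highest other 0) and 1 of 10 as many lists (13 and 11). In both cases the 1 is the real grouping. For the vehicle controls of the 3 experiments, too, only the real grouping, 1 of 100 splits, gave as many (733 and 236). Chance is thus an unlikely account there, though 1 of 100 is the smallest share these splits can give.

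Pmch, Oxt and Avp were high in the same 2 of the 3 pieces at 50 mg/kg, which may reflect more hypothalamic tissue in these pieces or a change with the dose. Of 37 hypothalamic markers written down for this test, 14 besides these 3 were measured (6 of them also in the gene lists), and 13 were higher, with Slc17a6 at 0.93 ± 0.55 and a median of 0.55, at percentile 100 of 10000 random lists matched on expression. Of 20 measured cortical markers (7 also in the gene lists) 18 were lower, with Tbr1 at -1.15 ± 0.34 and a median of -0.42, at percentile 0. The random lists were matched on mean expression only and do not vary together from piece to piece as regional markers can. The percentiles can therefore overstate how unusual both medians are. With the mean of Oxt and Avp as a covariate the change of Pmch went from 2.24 ± 0.38 to 1.21 ± 0.28, and its call ended (adjusted p = 0.484) with the smaller change. This test leaves both open and dose cannot be told apart from tissue in it, since the covariate is itself high in 2 of 3 dosed pieces. For this reason its criterion against a change with the dose was replaced after the value was seen. The first criterion, a change smaller than the unadjusted one by more than 2 standard errors, had been met. The criterion used instead, a change within 2 standard errors of 0, was not met.

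Immediate early genes were lower at 50 mg/kg, for which the tissue mixture of the pieces, 1 unusual vehicle array or an effect of dose could account. Leaving out any 1 vehicle array of experiment A kept the list past the threshold (adjusted p = 2.64e-06, 1.30e-04 and 5.79e-05 without animal 2, 3 or 4), which argues against 1 vehicle array as the cause. With the hypothalamic score as a covariate the list mean went from -0.34 ± 0.12 to -0.14 ± 0.12, and with 3 tissue scores to -0.13 ± 0.13. Dose and tissue mixture cannot be told apart here, since the smaller change lies within 2 standard errors both of 0 and of the unadjusted change.

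The 7 columns left out had r near 0 with the other arrays. Failed hybridization is excluded, since their median r with each other was 0.954 against 0.964 among the other arrays. A candidate explanation is that the values stand beside the wrong probe set names in an order the 7 share, which needs this high r among them; it was not tested against other causes of a shared order. No biological explanation was tested.

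Lists with no call for the trend were as follows, by adjusted p: mitochondrial respiratory chain 0.0589 (60 of 79 higher, Cox5a 0.08 ± 0.03), glucocorticoid-responsive genes 0.0609, cytoskeleton and axon growth 0.106 (Robo2 -0.09 ± 0.03) and inflammation 0.128. Immediate early genes and striatal markers had 0.135, ribosomal proteins 0.142, circadian clock genes 0.327, microglia markers 0.340, and xenobiotic metabolism (21 measured) and proteasome subunits (33) 0.368. Serine hydrolases that organophosphates can bind (10) had 0.377, heat shock and unfolded protein response 0.434, and the GABA system (17), meningeal and olfactory bulb markers 0.636. Apoptosis and cell cycle (29) had 0.833, cholinergic genes and choroid plexus markers 0.867, and neurotrophins and growth factors (16), neuropeptides, myelin and neuron markers (19) 0.874. Blood markers, with 3 measured, were not tested, and all 3 were lower at 30 mg/kg (median -0.79). Slc5a7, the choline transporter, chosen after its values were seen, was 1.47 ± 0.44 at 50 mg/kg and was the only cholinergic gene that passed there when adjusted over the list alone.

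Principal components 2, 3 and 4 over the 39 arrays held 10.4%, 7.78% and 6.66% of the variance. Oxt and Avp led component 2, and striatal genes such as Drd2 and Penk were among the leading genes of component 4. On component 2 the lowest array, and on component 3 the highest, was 1 mg/kg animal 1 of experiment C. It stood at -36.6 and 35.0, the next arrays being at -14.65 and 14.2, and its beta-actin 3'/5' ratio was 4.72. Components 2 and 3 therefore rest in part on this array.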
